A study of Mus musculus with 9 samples.

How the data were processed

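Sox2 ChIP-seq was done on mouse lung epithelial cells (C57BL/6, age 8 weeks per the labels) that were wildtype, carried ectopic Sox2, or carried ectopic Sox2 with deletion of Nkx2-1. Per the labels' protocols, cells were crosslinked with ethylene glycol bis(succinimidyl succinate) and formaldehyde, chromatin was sonicated and immunoprecipitated with a goat antibody against Sox2, and libraries were sequenced as single 50 bp reads. The series has 9 libraries, and the 3 Sox2 ChIP libraries have a peak list each. The input and IgG libraries were not analysed here, since no list was used for them.

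The submitters' processing notes name Bowtie2 2.2.9 (an aligner), SAMtools 1.4, MACS2 2.1.1 (a peak caller), HOMER 4.8.3 and the mouse genome build mm10. Each list was deposited per library, in the narrowPeak format of MACS2, so peaks were not called on pooled libraries. Which control, input or IgG, stood behind each list, the calling threshold, and any duplicate filter are not given in the sources used here. The authors' lists give, per summit, a score, a fold enrichment ratio over the local control background, −log10 p, −log10 q, and the region's and summit's positions. These per-summit scores, folds and −log10 values are the authors' own and were used here to describe, rank and filter summits within a list. Positions in the authors' lists count from 0 and are printed counting from 1. A region with several summits has a line for each, and each summit was counted.

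Fold and −log10 p together fix the ChIP pileup and the control background at a summit, because MACS2 writes the fold as (pileup + 1) / (background + 1) with a pseudocount of 1 and the p-value as a Poisson upper tail. Solving both, the ChIP pileups in each list were whole fragments times 1 scale (0.741 in wildtype, 0.638 with ectopic Sox2, 0.423 with Nkx2-1 deletion), with whole fragments taken within a tolerance of 0.02. Whole fragments were recovered for 100% of summits in the first 2 lists and a unique value for 99.8% in the last, leaving 6 summits with several solutions. The genome-wide control background divided by the scale gave the mean ChIP coverage: depth here is this recovered value and not a read total. Intervals on fragments are exact Poisson. Ratios between libraries at single regions were divided by the depth ratio, with an exact conditional binomial interval and no subtraction of the control background. Median ratios over regions found in every list, also scaled by depth, were taken after subtracting the control background. The 2 kinds of ratio can therefore differ for the same region.

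Genes were taken from a RefSeq table of the assembly GRCm38.p6, the same build as mm10, with 21887 protein-coding genes used. The table gives spans and no strand, so the planned distance to transcription starts was replaced. A gene was counted as near a summit when the summit lay inside its span or within 50 kb of it, and the planned promoter share became the share of summits within 1 kb of either end of a protein-coding gene. Exons and introns were not told apart. Motif shares at summits, planned for 20 motifs, were not run because no genome sequence was used here.

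Overlap was counted with bedtools 2.31.1 at a minimum of 1 bp, from each list's side, beside 1000 shuffles of the summits within their chromosome and within their annotation class. Random positions for annotation classes were drawn at 20000 per chromosome. For gene lists, the number of members near a summit was set beside 10000 random lists of the same size, matched on gene length in 20 bins, as a description of these libraries. The 16 main lists were fixed before the data were examined: alveolar type 2, alveolar type 1, airway secretory and ciliated, basal, squamous and oesophageal, gastric and intestinal, endoderm and lung transcription factors, pluripotency, neural Sox2 programme, Wnt, Notch, Fgf, Bmp and Hedgehog, cell cycle, housekeeping, immune, endothelium and mesenchyme. All of their entries matched a gene. A further 7 lists were written after the peak lists were seen and appear only in the closing observations. Sample groups, the main comparisons and the rule for named genes were also set before the data were examined; the thinning, the comparisons of fragments at single regions and the tests in the closing observations were not.

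Named genes are the Sox2 and Nkx2-1 loci, the nearest protein-coding gene of the 10 summits with the largest fold in each library, and the 10 of the highest-q summits without an overlapping region, in each direction between ectopic Sox2 with and without Nkx2-1 deletion. They also include up to 4 genes per fixed list by the largest −log10 q, and up to 15 genes nearest to regions found in all 3 lists. A nearest gene is the closest annotated span and need not be regulated by the site.

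To ask what depth alone gives, the recovered fragments of the Nkx2-1 deleted library were drawn binomially to the depth of another library, the control background was scaled, and summits were kept that passed the lowest −log10 p of the other list. There were 100 draws, and summits were not called anew. Alternatives tried were stricter −log10 q (at least 5) or fold (at least 5), overlap of at least 50% of both regions, and summits within 200 bp. Others were equal list lengths, lists without regions found in all 3, and gene windows of 10 and 100 kb. Nearest gene alone, with no limit of distance, and gene ends within 5 kb or of genes of any type were also tried. Random lists were not matched on the space around a gene, so shares by nearest gene give no chance level.

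The steps were tested on simulated data. Fold and −log10 p made from known fragments at 552, 229 and 2589 summits gave the right fragments for 100% of them. An overlap planted at 40.2% of regions was recovered as 40.2%. Of 300 random gene lists, 4.33% fell among the highest 5% of random lists. A planted list of 25 genes with 15 near a summit exceeded all random lists. These lists were drawn gene by gene, so they do not test lists whose neighbouring genes share a summit. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.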

Results

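Sox2 binding was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in mouse lung epithelial cells of the C57BL/6 strain. Sox2 is a transcription factor of the foregut, where it marks the proximal airway and the oesophagus, and Nkx2-1 is the transcription factor that sets lung identity. The labels name wildtype cells, cells with ectopic Sox2, and cells with ectopic Sox2 and deletion of Nkx2-1. The series holds 9 libraries, 1 each of input, IgG and Sox2 ChIP per condition, and the 3 Sox2 ChIP libraries each have a list of binding summits. Because each condition has 1 library, no difference between conditions has a replicate check and no p-value is given between them. Intervals are exact binomial or Poisson 95% intervals and cover counting error only. Those on the chromosome 19 control background are instead 95% bootstrap intervals, which resample summits as if independent. A peak list carries no expression value, so the presence of ectopic Sox2 and the loss of Nkx2-1 were taken from the labels.

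The wildtype list held 552 summits in 545 regions, the ectopic Sox2 list 229 summits in 228 regions, and the list for ectopic Sox2 with Nkx2-1 deletion 2589 summits in 2551 regions. Their median region widths were 243 bp, 230.5 bp and 256 bp. The median fold enrichment, a value the authors' peak caller gives each summit within its own list, was 5.80 in wildtype, 6.56 with ectopic Sox2 and 5.73 with Nkx2-1 deletion. The ChIP depth implied by the listed values was a mean coverage of 0.963 fragments per position in wildtype, 0.764 with ectopic Sox2 and 1.45 with Nkx2-1 deletion. The Nkx2-1 deleted library was therefore 1.90 times as deep as the ectopic Sox2 library and 1.51 times as deep as wildtype. A summit rested on a median of 24 ChIP fragments in wildtype, 23 with ectopic Sox2 and 38 with Nkx2-1 deletion.

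The Sox2 and Nkx2-1 loci carried no listed summit within 50 kb in any of the 3 libraries. On chromosome 3, where Sox2 spans 34649995 to 34652461 (mm10), the nearest summit lay 573 kb away in wildtype and 1071 kb away in both other libraries. On chromosome 12, where Nkx2-1 spans 56531935 to 56536908, the nearest summit lay 271 kb away in wildtype, 1245 kb with ectopic Sox2 and 174 kb with Nkx2-1 deletion.

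The main comparison set ectopic Sox2 with Nkx2-1 deletion beside ectopic Sox2 alone, and asked where Sox2 bound with and without Nkx2-1. With Nkx2-1 deletion, summits lay near Trp63, the master regulator of basal and squamous epithelium, near the desmosomal cadherin genes Dsg3 and Dsc3, and near Klf5, none of which had a summit within 50 kb in the ectopic Sox2 list. Of all protein-coding genes, 13.1% had a summit within 50 kb with Nkx2-1 deletion, 1.53% with ectopic Sox2 and 2.85% in wildtype. Absence from the ectopic Sox2 list is thus the usual case for a gene. The wildtype list had a summit within Trp63 and another near Dsg3, and the ectopic Sox2 list had a summit near Krt5 and Krt6a. The Nkx2-1 deleted list was 11.3 times as long as the ectopic Sox2 list. Thinned in silico to the ChIP and control depth of the ectopic Sox2 library, 2147 summits (SD 13.7 over 100 draws) still passed that library's lowest listed value, against the 229 it lists. This thinning was chosen after the lists were seen.

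**Figure D1:**
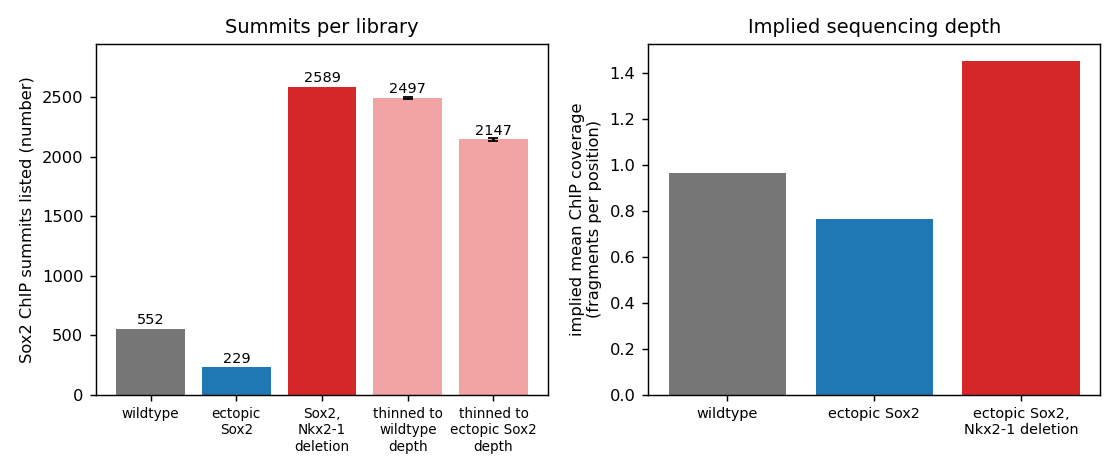
Left, number of Sox2 ChIP summits listed in each library, 1 library per condition, and in pale red the number left when the Nkx2-1 deleted library is thinned to the depth of another library (mean over 100 draws, bars are the SD over draws). Right, ChIP depth implied by the listed values, as mean fragments per position. The thinned numbers, 2497 and 2147, stay above the 552 and 229 summits of the other lists.

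By the authors' fold, the leading summit with Nkx2-1 deletion lay within Sox5, a Sox family factor of cartilage and neural development, at chromosome 6, 144021724 to 144022028, with a fold of 19.97 and 92 fragments (interval 74.2 to 113). The next, with a fold of 17.4 and 121 fragments (100.4 to 145), lay at chromosome 10, 44716627 to 44717042, where the nearest protein-coding gene is Prdm1, a repressor active in terminal epidermal differentiation, 188 kb away. Summits nearest to Dennd11, Dcbld2, Tulp4, Tgm3, Cdc14b, Btrc, Gm2016 and Slc25a21 completed the leading 10, with folds from 16.2 to 14.3. Tgm3 encodes a transglutaminase of the cornified envelope, and its summit lay 58.9 kb from the gene. Ranked by q among summits with no overlapping region in the ectopic Sox2 list, Prdm1 and Sox5 were followed by Anxa1, which encodes annexin A1, with 140 fragments (118 to 165) at chromosome 19, 20406566 to 20407000. Gm2016, Btrc, Tulp4, Cdc14b, Id2, Cntnap2 and Bcl2l14 made up the rest. Of these 10 summits, those of Sox5, Anxa1, Gm2016 and Id2 overlapped a wildtype region. On chromosome 19, which holds Anxa1 and Btrc, the recovered control background at listed summits was 1.51 times (1.32 to 1.71) that at summits on the other autosomes in the Nkx2-1 deleted library, and 1.36 times (0.808 to 1.94) in wildtype.

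In the other direction, the leading ectopic Sox2 summits with no overlapping region in the Nkx2-1 deleted list were mostly at the ends of genes. They were nearest to Galntl6, Znhit3, Snrpb2, Ino80, Palb2, Snx18, Mycn, Ttc37, Fan1 and Cspg4, and 7 of the 10 lay within 1 kb of an end of the gene span. Znhit3 had a fold of 14.9 and 45 fragments (32.8 to 60.2) at chromosome 11, 84916254 to 84916568, 60 bp from the gene. Palb2, a partner of the DNA repair protein Brca2, had 63 fragments (48.4 to 80.6) at chromosome 7, 122132842 to 122133128. Those of Galntl6, Snrpb2, Palb2 and Mycn overlapped a wildtype region.

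Of the 16 gene lists, the list of basal, squamous and oesophageal genes had the most members near a summit with Nkx2-1 deletion. A summit lay within 50 kb of 15 of its 25 genes, against a mean of 3.04 for random lists matched on gene length (central 95% range 0 to 6), and none of the 10000 random lists reached 15. The same list had 2 genes with ectopic Sox2 alone (random mean 0.367), which 4.85% of random lists reached. In wildtype it had 3 (random mean 0.624), which 2.1% reached. Set against its own random mean, the basal count was raised to a similar degree in each library, but on few genes with ectopic Sox2 and in wildtype. The 2 ectopic Sox2 genes, Krt5 and Krt6a, shared 1 summit. The ectopic Sox2 count was 1 within 10 kb (16.9% of random lists), 2 within 100 kb (12.6%) and 1 by nearest gene (21.2%). Without regions found in all 3 lists it was 2 (3.53%). With Nkx2-1 deletion, Trp63 had 5 summits within the gene. The highest by q lay at chromosome 16, 25780113 to 25780525, with a fold of 9.03 and 83 fragments. The wildtype list had 1 summit there, with 19 fragments, a depth-scaled ratio of 2.90 (interval 1.74 to 5.05) between the Nkx2-1 deleted and wildtype libraries. That region was picked as the highest by q with Nkx2-1 deletion, which favours a high ratio. Dsg3 had 2 summits, the stronger 183 bp from the gene at chromosome 18, 20509958 to 20510255, with a fold of 11.8 and 59 fragments. Dsc3 had 3 summits, the strongest within the gene at 19993153 to 19993484 with a fold of 9.60, and Klf5, a factor of proliferating epithelium, had 2, the stronger within the gene with a fold of 5.79. Chosen after their values were seen, the other 11 genes were Fgfr2, Sox15, Ivl, Itga6, Krt5, Krt6a, Ngfr, Krt14, Krt15, Krt13 and Perp.

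**Figure D2:**
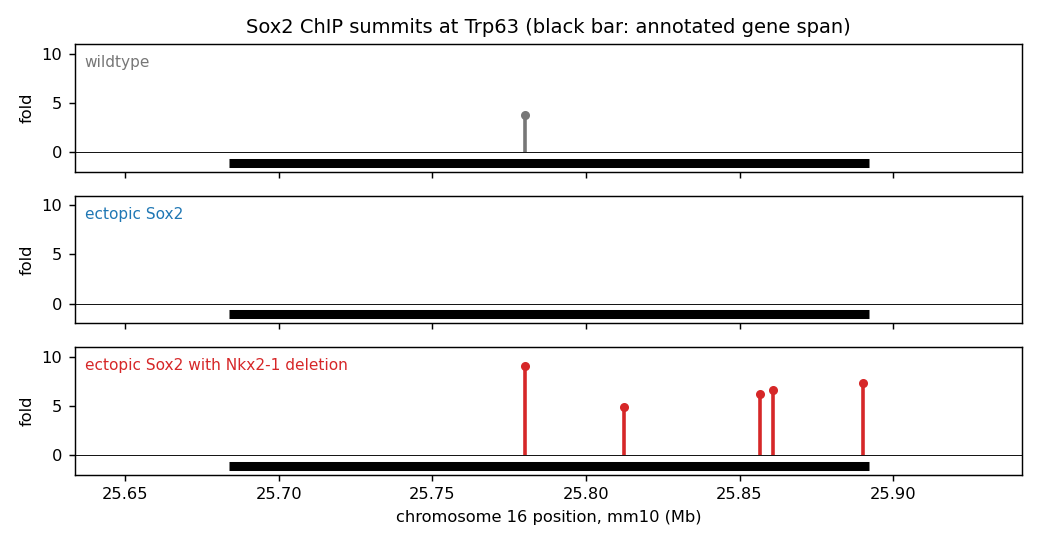
Sox2 ChIP summits at Trp63 in each of the 3 libraries, by mm10 position on chromosome 16 (Mb) and the authors' fold enrichment; the black bar is the annotated gene span. The Nkx2-1 deleted list has 5 summits, the wildtype list 1 and the ectopic Sox2 list none.

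The basal count with Nkx2-1 deletion stayed above random lists under other gene windows, but it depended on weak summits. It was 7 within 10 kb (random mean 1.32), 17 within 100 kb (5.04) and 15 without regions found in all 3 lists (2.99). By nearest gene it was 10 (1.84), a setting that gives no chance level. No random list reached any of these counts, but these settings keep the weak summits. With summits of −log10 q of at least 5 alone, 4 of the 25 genes remained near a summit (Trp63, Dsg3, Dsc3 and Klf5), and 13.7% of random lists had as many, against 2 genes with ectopic Sox2 alone, which 3.37% of random lists reached. Neighbouring genes also share summits, so that Krt13, Krt14 and Krt15 rested on 1 summit of −log10 q 1.45 and Krt5 and Krt6a on another, which the ectopic Sox2 list also held, and the 15 genes rested on 21 separate summits.

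Alveolar type 1 genes, which mark the flat gas-exchange cell, had a summit near 7 of 14 members with Nkx2-1 deletion (random mean 1.90), and 0.07% of random lists had as many. Ahnak had 6 summits, the strongest with a fold of 5.65 and 91 fragments at chromosome 19, 9071501 to 9071823, on the chromosome with the higher control background at summits. Clic5, Gprc5a and Spock2 had 1 summit each, with 52, 65 and 33 fragments. The list had 1 gene in wildtype, Clic5 (random mean 0.42), which 35% of random lists reached. It had 0 with ectopic Sox2 alone (random mean 0.218), as did 80.4% of random lists. These shorter lists therefore leave little room for a count to differ from random. Within 10 kb the count was 2 of 14, which 23.4% of random lists reached. By nearest gene it was 3, which 11.2% reached, and with −log10 q of at least 5 it was 4, which 2.95% reached. Within 100 kb and without regions found in all 3 lists the Nkx2-1 deleted count was 7, which 1.86% and 0.07% reached.

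Notch pathway genes, which govern airway cell fate choices, had a summit near 6 of 18 members with Nkx2-1 deletion (random mean 2.37), and 2.01% of random lists had as many. By −log10 q the leading 4 were Lfng at 10.4, Maml2 at 9.66, Nrarp at 9.60 and Dll1 at 7.80. With ectopic Sox2 alone 3 of 18 had a summit, Nrarp, Notch2 and Dll1, which 0.22% of random lists reached, and wildtype had Nrarp alone. With −log10 q of at least 5 the ectopic Sox2 count was 1, which 20.6% of random lists reached. Under the other settings the ectopic Sox2 count was 2 within 10 kb (0.88%), 3 within 100 kb (1.1%), 2 by nearest gene (1.33%) and 2 without regions found in all 3 lists (1.88%). Without regions found in all 3 lists the Nkx2-1 deleted count was 5, which 6.59% of random lists reached, and within 100 kb it was 7, which 6.78% reached. With −log10 q of at least 5 and by nearest gene it was 6, which 0.21% and 0.08% of random lists reached. At Nrarp, a feedback inhibitor of Notch signalling, the region at chromosome 2, 25180595 to 25180849 had a depth-scaled ratio of 0.701 (0.462 to 1.07) between the Nkx2-1 deleted and ectopic Sox2 libraries, an interval that includes 1, and of 0.538 (0.372 to 0.777) between the Nkx2-1 deleted and wildtype libraries. Nrarp was compared in this way after its values were seen, as was Trp63.

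At 50 kb, the other fixed lists had counts with Nkx2-1 deletion within the central range of random lists, and 3 of them left it under other settings. Wnt pathway genes had a summit near 8 of 28 members, which 8.18% of random lists reached, led by Wnt7a with 64 fragments within the gene and by Fzd7, Tcf7l2 and Fzd1. Tcf7l2 lies on chromosome 19. By nearest gene the Wnt count was 9, which 0.33% of random lists reached. Airway secretory and ciliated genes had 5 of 18 (9.18%), namely Scgb1a1, Tubb4b, Rfx3, Aldh1a1 and Cyp2f2. Scgb1a1, Rfx3 and Aldh1a1 lie on chromosome 19, and the 4 summits counted for Scgb1a1, the club cell secretoglobin, are also counted for Ahnak. The airway count was 4 within 10 kb (2.31%) and 8 within 100 kb (2.4%). Endoderm and lung transcription factors had 7 of 26 (10.3%), led by Irx2, Klf5, Tead1 and Foxa1. Their count was 6 within 10 kb (2.73%), 11 within 100 kb (2.49%) and 5 with −log10 q of at least 5 (15.4%). By nearest gene it was 12, which none of the 10000 random lists reached. A nearest gene can lie at any distance, and random lists were matched on gene length and not on the space around a gene. Genes with much space around them can therefore collect distant summits. Shares by nearest gene, here and for the other lists and libraries, thus give no chance level.

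Alveolar type 2 genes, which include the surfactant genes and depend on Nkx2-1 in the normal lung, had 1 of 18 near a summit, Il33 on chromosome 19, against a random mean of 2.17. Gastric and intestinal genes, which Nkx2-1 represses in lung tumours, had 1 of 29, Krt20, with 97.6% of random lists at least as high. Pluripotency genes had 2 of 16, Nanog and Zfp42, and neural Sox2 programme genes had 1 of 17, Fabp7. Fgf, Bmp and Hedgehog pathway genes had 2 of 27, Dusp6 and Fgfr2. Cell cycle genes had 1 of 20, Rb1, with 109 fragments. Housekeeping genes had 3 of 20, Tbp, Tubb5 and Eef2. For other cell types a preparation could hold, immune genes had 1 of 12, Cd68, on the same summit as Sox15, endothelial genes 1 of 12, Vwf, and mesenchymal genes 1 of 14, Dcn.

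**Figure D3:**
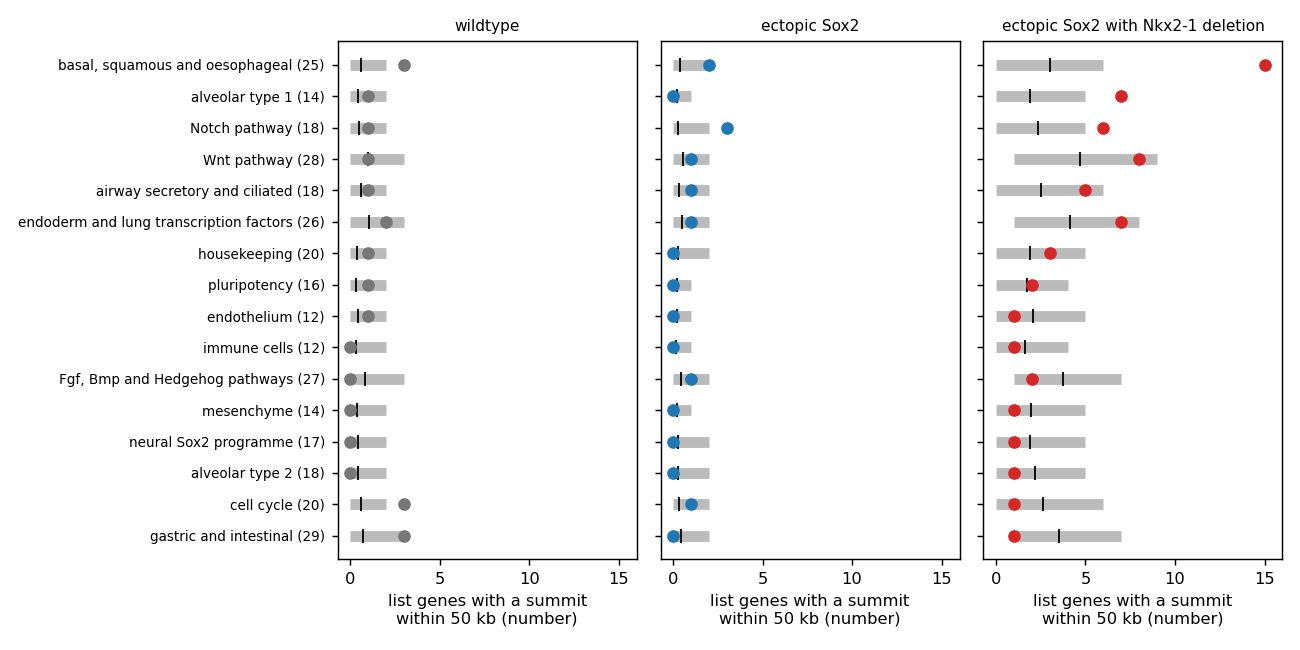
Number of genes of each fixed list (list size in brackets) with a Sox2 summit within 50 kb of the gene span, per library. Dots are the observed counts, black ticks the mean and grey bars the central 95% of 10000 random lists matched on gene length. The basal list has 15 genes near a summit with Nkx2-1 deletion, outside the grey bar of 0 to 6. In wildtype it has 3, also outside its bar of 0 to 2.

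The comparison of ectopic Sox2 with wildtype addressed where Sox2 bound once expressed ectopically. The leading summit by fold was the same region in both, 18.3 kb from Klf13, a zinc-finger transcription factor gene, at chromosome 7, 63957094 to 63957379 with ectopic Sox2, with 36 fragments there and 67 in wildtype. The other leading ectopic Sox2 summits were nearest to Znhit3, Galntl6, Vsnl1, Pdcd5, Mycn, Clrn1, Tbl1xr1, Fam91a1 and Cspg4, with folds from 14.9 to 11.6. In wildtype, Klf13 was followed by Nrarp, at 13.0 and 69 fragments (53.7 to 87.3), and then by Ppp2r2b, Cbl, Tjp1, Ctsl, Ccdc150, Gm6958, Api5 and Aldh8a1. Ppp2r2b, Cbl and Tjp1 had no region in another list.

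Gene ends set the ectopic Sox2 list apart. Of its summits, 14.4% (interval 10.1 to 19.6) lay within 1 kb of either end of a protein-coding gene, against 4.35% (2.81 to 6.40) in wildtype, 3.48% (2.80 to 4.26) with Nkx2-1 deletion and 3.07% of random positions matched to the ectopic Sox2 list. Among the 72 ectopic Sox2 summits with no region in another list the share was 23.6% (14.4 to 35.1). Within genes, away from the ends, lay 44.6% of wildtype summits, 35.8% with ectopic Sox2 and 46.9% (44.9 to 48.8) with Nkx2-1 deletion, where random positions gave 38.5%. The annotation used here gives no strand, so starts and ends of genes were not told apart.

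The ectopic Sox2 list had fewer summits than wildtype, 0.415 times as many at 0.793 times the depth. In wildtype, 3 fixed lists had more members near a summit than the central range of random lists or lay at its edge. Basal genes had 3 of 25 (Dsg3, Perp and Trp63), which 2.1% of random lists reached, but 1 within 10 kb (23.8%) and 1 with −log10 q of at least 5 (35.0%). The basal count was 4 within 100 kb (2.19%), 3 by nearest gene (1.14%) and 3 without regions in all 3 lists (1.34%). Cell cycle genes had 3 of 20 (Mycn, Rb1 and Cdk6), which 1.74% reached, with 2 at −log10 q of at least 5 (5.88%), 3 within 100 kb (6.91%), 2 within 10 kb (2.55%), 3 without regions in all 3 lists (1.38%) and 4 by nearest gene (0.07%). Gastric and intestinal genes had 3 of 29, the trefoil factor genes Tff1, Tff2 and Tff3, on 1 shared summit, and 0 within 10 kb or by nearest gene. With ectopic Sox2, the 2 basal genes, Krt5 and Krt6a, likewise shared 1 summit, 254 bp from Krt6a.

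The lists shared regions at which binding was found in all 3 libraries. Such regions held 63 wildtype summits, 63 ectopic Sox2 summits and 62 summits with Nkx2-1 deletion. By q in the last, the nearest genes were Runx2, Ccm2, Gm44812, Marchf6, Dennd11, Abcc4, Klf13, Aldh8a1, Tnc, Mtf2, Kcna5, Runx1, Fam91a1, Dnajc18 and Aspa. At Runx2, a factor of bone formation, the region at chromosome 17, 44548010 to 44548372, lies within the gene and had 146 fragments with Nkx2-1 deletion, 53 with ectopic Sox2 and 58 in wildtype. Scaled by depth, the Nkx2-1 deleted library had 1.45 times (1.05 to 2.02) the ectopic Sox2 fragments and 1.67 times (1.22 to 2.30) the wildtype fragments there. At Ccm2 the ratios were 3.53 (2.11 to 6.27) and 2.04 (1.4 to 3.05), and at Aspa 0.931 (0.674 to 1.30) and 1.07 (0.781 to 1.47). Ranking by q in the Nkx2-1 deleted list favours high ratios, and the intervals do not cover that choice. Over all 62 regions compared, the median ratios were 1.22 over ectopic Sox2 and 1.27 over wildtype, with the control background subtracted.

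Of the 229 ectopic Sox2 summits, 119 overlapped a region of the Nkx2-1 deleted list (52.0%, interval 45.3 to 58.6) and 101 a wildtype region (44.1%, 37.6 to 50.8). Of the 552 wildtype summits, 273 overlapped a region of the Nkx2-1 deleted list (49.5%, 45.2 to 53.7) and 101 an ectopic Sox2 region (18.3%, 15.2 to 21.8). From the longer list, 10.5% (9.39 to 11.8) of the summits with Nkx2-1 deletion overlapped a wildtype region and 4.60% (3.82 to 5.48) an ectopic Sox2 region. Shuffled within their chromosomes, at most a mean of 0.286 summits overlapped. Summits with no region in another list made up 43.7% (39.5 to 47.9) in wildtype, 31.4% (25.5 to 37.9) with ectopic Sox2 and 87.3% (85.9 to 88.5) with Nkx2-1 deletion. The order of these shares changed with list length. With each list reduced to its leading 229 summits by q, 27.9% (22.2 to 34.2) of ectopic Sox2 summits overlapped a wildtype region and 11.8% (7.92 to 16.7) a region with Nkx2-1 deletion, the opposite order to that of the full lists.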

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

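The alternatives that thin the Nkx2-1 deleted library, count regions once or count separate summits were chosen after seeing the data. Of 361 alternative values, 103 moved beyond 1.5 times a count or beyond a share's counting interval. With −log10 q of at least 5 the lists fell to 327 summits in wildtype and 1616 with Nkx2-1 deletion, and the shares overlapping the Nkx2-1 deleted list were 42.5% of wildtype and 43.8% of ectopic Sox2 summits. At equal list lengths these were 15.7% and 11.8%, and 27.9% of ectopic Sox2 summits overlapped wildtype. Without regions in all 3 lists, by construction fewer, they were 42.9% and 33.7%, and 22.9% for wildtype. Shares near gene ends within 5 kb were 12.7% in wildtype, 23.1% with ectopic Sox2 and 14.2% with Nkx2-1 deletion, and with genes of any type 8.51%, 19.7% and 7.84%; both widen what counts as a gene end. The ectopic Sox2 share was the highest of the 3 under each of the 4 alternatives run for gene ends. Basal list genes with Nkx2-1 deletion numbered 7 within 10 kb and 4 with −log10 q of at least 5. In wildtype both settings left 1 gene, and with ectopic Sox2 1 gene was left within 10 kb and by nearest gene, on 1 separate summit. For the other 15 fixed lists, 73 of 285 values moved, 36 up and 37 down. From the longer list of a pair, 7 of 15 shares moved, 3 up and 4 down. Stricter q and equal lengths leave fewer summits by construction, narrower windows fewer genes; for the nearest gene the cause was not tested. Motif alternatives were not run, for want of a genome sequence here. The ectopic Sox2 library was the shallowest, at 0.764 fragments per position. No paired analysis was possible because each condition has 1 library.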

Other observations

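The 7 gene lists described first were written after the peak lists were seen, when summits near some members (Trp63, Dsg3, Dsc3, Itga6, Sox5, Sox15, Prdm1, Tead1) were already known, so their shares of random lists describe and give no chance level; the thinning tests and the test of an extra copy of chromosome 19 were chosen only after the result was seen.

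With Nkx2-1 deletion, genes of hemidesmosomes and desmosomes, the junctions that anchor basal and squamous cells, had a summit within 50 kb of 10 of 16 members (random mean 2.86), on 12 separate summits. Among them were Col17a1 with 47 fragments on chromosome 19 and Pkp1 with 2 summits, beside Dsg3, Dsc3 and Itga6, which the basal list also holds. Dsg2 shared a summit with Dsg3, and Dsc2 with Dsc3, so that 5 of the 10 rest on summits the basal list had already shown. Targets of Nrf2, the regulator of the oxidative stress response, had 6 of 12 (0.28% of random lists as high), among them Aldh3a1 with 60 fragments, Gclm with 68 and Gclc with 44. Egf receptor ligands and receptors had 5 of 12 (5.38%), with Tgfa carrying 3 summits and Areg and Ereg sharing 1. Squamous transcription factors had 3 of 16 (Trp63, Prdm1 and Grhl1), Hippo pathway genes 3 of 14 (Ccn2, Tead1 and Yap1) and Eph receptors and ephrins 2 of 19 (Epha1 and Epha4), each within the range of random lists. The hemidesmosome and desmosome list was also high in wildtype, with 3 of 16 (Lama3, Col17a1 and Dsg3, random mean 0.627), which 2.15% of random lists reached. With ectopic Sox2 it had 1 (27.5%).

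The Sox family had 3 of 18 members near a summit with Nkx2-1 deletion, yet on 13 separate summits, 9 of them at Sox6. Sox6 had the most summits of any protein-coding gene in that list, against 3 in wildtype and 2 with ectopic Sox2, and Sox5 had 3, 3 and 1. Sox6 is a long gene, at chromosome 7, 115470872 to 116040776. The Nkx2-1 deleted list is 11.3 times as long as the ectopic Sox2 list and 4.69 times as long as wildtype. Relative to list length, neither Sox6 nor Sox5 had more summits with Nkx2-1 deletion than in the other lists. In wildtype 3 of 18 Sox genes had a summit (Sox5, Sox6 and Sox21), which 0.99% of random lists reached. At the strongest Sox6 region the depth-scaled ratio of fragments between the Nkx2-1 deleted and wildtype libraries was 2.95 (1.90 to 4.75). It was picked as the strongest with Nkx2-1 deletion, which favours a high ratio. Sprr2a2, from the cluster of small proline-rich genes of the cornified envelope, had 6 summits with Nkx2-1 deletion, 2 with ectopic Sox2 and 0 in wildtype. Relative to list length, Sprr2a2 had fewer with Nkx2-1 deletion than with ectopic Sox2. Its neighbours are near-identical copies, and how reads were placed between them was not examined here. These genes were chosen after their values were seen.

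The long list with Nkx2-1 deletion was set against depth and pull-down. Depth alone is argued against, since 2146.57 summits (SD 13.7) were left at the ectopic Sox2 depth, where a count of at most 343.5 was needed, and 2496.88 at the wildtype depth. At the ectopic Sox2 depth 10.41 basal genes (SD 1.87) were left, against 2 with ectopic Sox2. That thinned list was still 9.37 times as long as the ectopic Sox2 list, so the basal count adds nothing on depth beyond the summit count. A pull-down that recovers every site better had some support. Regions in all 3 lists had a median log2 ratio of 0.29 (SE 0.06) over ectopic Sox2, higher at 46 of 62. This SE was taken over regions and does not cover variation between libraries. Depth and that ratio plus 2 SE together left 1305.59 summits (SD 20.6), but this excludes nothing, because the ratio was measured where ectopic Sox2 had passed and so understates a pull-down difference. A better pull-down with depth, loss of Nkx2-1, which the design names, and a difference between cell preparations or controls therefore cannot be told apart with 1 library per condition.

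Regions found in all 3 lists include wildtype, where no Sox2 was added. If binding there followed the Sox2 level and both pull-downs were equally good, ectopic Sox2 would exceed wildtype. The median log2 ratio between them was 0.0428 (SE 0.06 over regions), higher at 33 of 62 regions. The ratio was scaled by depth and not by pull-down, so a poorer pull-down with ectopic Sox2 could hide a rise. The regions were chosen as called in every list, which draws such ratios together. The value therefore cannot exclude binding that follows the Sox2 level. It also fits sites recovered whatever the Sox2 level, such as open or sticky chromatin or binding by endogenous Sox2. The test cannot part these, and the Sox2 protein level was not measured here.

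Chromosome 19 held 5.41% of summits with Nkx2-1 deletion and 2.72% in wildtype, and 1 summit (0.437%) with ectopic Sox2. Gene density did not track the summit share over wildtype (Spearman rho 0.0386 across the 19 autosomes, permutation p = 0.879, adjusted 0.879, and Pearson r 0.176). With 19 points a moderate relation is not excluded. Chromosome 19 itself has 12.2 protein-coding genes per Mb, and a correlation over all autosomes cannot decide for it alone. Chromosome copy number in the control could not be decided (rho 0.379, permutation p = 0.110, adjusted 0.220; Pearson r 0.680, permutation p = 0.00404, adjusted 0.00808, and r 0.194 without chromosomes 19 and 4, on which the relation rests). The control background at summits was 1.51 times as high on chromosome 19 as on the other autosomes (bootstrap interval 1.32 to 1.71), which fits an extra copy as a candidate explanation, though the wildtype ratio of 1.36 (0.808 to 1.94) over 15 summits does not exclude the same there. A gain in these cells or a local property of the chromosome remain possible.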
